A study of Homo sapiens with 4 samples.

How the data were processed

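Chromatin immunoprecipitation sequencing (ChIP-seq) was carried out in SUM159, an established human breast cancer cell line. The labels give 2 ChIP samples from cells with a FLAG-tagged POGK construct in the pLVX vector and 2 samples titled as input from cells with the pLVX FLAG vector. Per the labels' protocols, cells were crosslinked with formaldehyde, chromatin was sonicated, DNA was recovered with magnetic antibody beads, and libraries were sequenced as read pairs and aligned to hg38. The antibody is not named in the sources used here.

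One peak list and one table of program settings were analysed for the whole series. Per the deposited settings table, duplicate reads were removed with clumpify, reads were trimmed with bbduk and Trimmomatic, aligned with BWA-MEM and filtered at a mapping quality of 10. Peaks were called with MACS2, SICER2, HOMER and Genrich, merged with HOMER and annotated with HOMER, per the same table. The table also lists GEM, which the caller column of the peak list does not name. The submitters' processing notes name BWA, MACS2, SICER, HOMER, Genrich and hg38, without versions. How reads shared between copies of repeated sequence were placed was not tested, so values at satellites, ribosomal DNA and gene families are uncertain.

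The deposited control column holds the count of control tags per peak, in whole numbers, as the authors gave it. The ChIP column is a signal that the authors scaled to the control by uniquely mapped depth, per the settings table. Of the 203 ChIP values below 60, 99.0% were whole multiples of 0.792 within 0.0051, so ChIP tags were 1.26 times as deep as control tags before scaling. The deposited fold is the ratio of the scaled ChIP signal to the control count and matched that quotient within 0.006 in every peak with control tags. A deposited −log10 IDR column was read but enters no result. The authors' GC fraction per peak matched hg38 within 0.0001 in 99.8% of peaks when intervals were read as 1-based and closed, against 35.6% when read as 0-based. Coordinates are therefore printed as deposited. The number of callers, distance to the nearest transcription start site (TSS), annotation, repeat and gene name of each peak are also the authors' deposited values. The distance runs from the peak centre to the nearest RefSeq TSS.

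Each peak has 1 ChIP value and 1 control value, so the replicates were combined before deposit and no spread between replicates could be computed. No test between groups was therefore made, and depth per sample is unknown. The peaks held 28602086 control tags and 30677419 scaled ChIP tags. Intervals on folds are 95% exact (Clopper-Pearson) binomial intervals of the share of ChIP tags, converted to a fold, and intervals on shares of peaks are exact binomial intervals. Both cover counting error only. A median control count of 413 tags per peak, with 94 at the 5th percentile and 1623 at the 95th, sets their width. Intervals on a median fold come from 1000 bootstrap draws of peaks. ChIP and control differ both in immunoprecipitation against input and in POGK-expressing against vector cells, so a fold mixes both differences.

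The shares of peaks near a protein-coding TSS (GENCODE 44) were set beside 100 random placements of the same intervals on the same chromosome outside assembly gaps. Gene lists were fixed before the data were examined, as were the named genes, the comparisons and most alternative settings; the others were chosen after seeing the data. For each of 27 lists with at least 10 genes, the percentage of genes with a peak centre within 1 kb of the TSS was compared with 10000 random lists. These had the same size and were matched on gene-length decile, from 19982 protein-coding genes, or 18818 lncRNA genes for the snoRNA host list. Two-sided tail shares were adjusted by Benjamini-Hochberg over the lists and describe this peak list only. Genes were drawn independently, although neighbouring genes can share a peak, so tail shares of gene families in clusters can be too small. Of 9446 protein-coding symbols in the peak list, 99.1% matched the annotation. The lists were ribosomal proteins of each subunit, ribosome biogenesis factors, RNA polymerase I and III, mitochondrial ribosomal proteins, translation factors, KAP1 and heterochromatin, pogo and Tigger derived genes, MYC and mTOR growth, p53 targets, cell cycle, basal, luminal, immune, neuron and liver markers, histones, snoRNA hosts, DNA repair, proteasome, oxidative phosphorylation, ZNF genes, olfactory receptors, keratin-associated proteins, protocadherins and solute carriers. POGK itself was list 28 and was not tested. Alternatives changed the number of callers, the fold, the TSS window, the overlap rule and the matching, and the lists were compared in 13 settings. Those that needed values per sample were not run. The rule for when a list changed sides was revised after its first outcome: a list without a call in either setting is now counted as unchanged whatever its side of the random mean, and alternatives where random lists held under 1 gene with a peak on average gave no value. The main value of the snoRNA host list, which held 0.469, was kept. RefSeq names 96.2% of the protein-coding background and 28.6% of the lncRNA background, so an alternative drew random lists from named genes only.

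Named genes were the 10 highest folds among protein-coding promoter peaks of all 4 callers, the 5 highest folds among all peaks of 4 callers, up to 4 promoter members per list ranked by callers and then fold, POGK and related genes, and MYC and the ribosomal, 5S, 7SK and small nuclear RNA genes named by a peak. Only 1 gene met the first part. One of the 5 strongest peaks lies on chromosome Y and is not described. One promoter peak with a fold of at least 1.5 is counted but not reported by name here. In tests on simulated peak status over 19982 genes with lists of 40 genes, 2% of 100 unchanged lists, 31% of lists with doubled odds (odds multiple 2) and 98% of lists with an odds multiple of 4 had a tail share under 0.05. The simulated lists were drawn at random with independent peak status, and their tail shares were not adjusted. These rates therefore do not cover families of neighbouring genes or the adjusted threshold. Fold intervals covered the simulated fold in 95.8% to 96% of 500 runs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.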

Results

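The series mapped chromatin binding of POGK (pogo transposable element derived with KRAB domain) in SUM159 breast cancer cells. POGK joins a KRAB domain to a pogo-like transposase sequence. The design compared ChIP DNA of 2 samples of POGK-expressing cells with 2 input samples of vector cells, to find the DNA that POGK binds, and the series title points to ribosome biogenesis. The deposited list held 40721 peaks over 213.8 Mb of hg38. The replicates were combined in 1 ChIP and 1 control value per peak, so no value below has replicate error and the intervals cover counting error only.

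Most peaks were broad and had ChIP signal close to control. Their median length was 4000 bp, from 600 bp at the 5th percentile to 13400 bp at the 95th. The median fold of scaled ChIP tags over control tags, the authors' own value per peak, was 1.09, with 0.91 at the 5th percentile and 1.58 at the 95th. In 8111 peaks (19.9%, 95% interval 19.5 to 20.3) the ChIP signal was below control. A fold of at least 2 was reached by 892 peaks (2.19%, 2.05 to 2.34) and a fold of at least 4 by 22 peaks. The counting interval of the fold lay above 1 in 16121 peaks, below 1 in 1404 and included 1 in 23196. SICER2 alone called 38739 peaks (95.1%, 94.9 to 95.3). At least 2 callers shared 1196 peaks (2.94%), at least 3 shared 128 and all 4 shared 29. The 610 peaks of MACS2 alone had a median fold of 2.14 and a median length of 332 bp, against 1.09 and 4000 bp for SICER2 alone. No peak had a motif listed.

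Among the 29 peaks called by all 4 callers, the highest fold was at HBB, the beta-globin gene. This peak on chromosome 11, from 5224800 to 5227199, had a fold of 4.21 (3.64 to 4.90), with 898 scaled ChIP tags against 213 control tags, and its centre lay in intron 2. Next came an alpha satellite on chromosome 1, from 121774800 to 121776020, nearest to the pseudogene EMBP1, with a fold of 2.90 (2.32 to 3.67). A peak at the promoter of the non-coding gene FAM230E on chromosome 22, from 18733000 to 18734293, had a fold of 1.68 (1.54 to 1.83). An intergenic peak on chromosome 1, from 143210800 to 143223799 and nearest to LSP1P5, had a fold of 1.51 (1.49 to 1.53). By the authors' distances, the only protein-coding promoter with a peak of all 4 callers was that of MTRNR2L1, a humanin-like gene that resembles mitochondrial rRNA, on chromosome 17 from 22519800 to 22525399. Its fold was 1.15 (1.14 to 1.17) over 38972 control tags.

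POGK itself carried 3 peaks, each overlapping an exon. The gene lies on chromosome 1 from 166839447 to 166856359. The peak over exon 5, from 166848400 to 166850599, had a fold of 1.90 (1.72 to 2.11) and was called by MACS2, SICER2 and Genrich. The peak over exon 2, from 166840200 to 166841199, had a fold of 1.5 (1.23 to 1.83), and that over exons 3 and 4, from 166845400 to 166847599, a fold of 1.48 (1.27 to 1.73). Every one of the 4 coding exons had a peak. Exon 6, which is untranslated and runs from 166852585 to 166856359, had none, and the sole other peak within 1 Mb had a fold of 1.0 (0.875 to 1.14). Of the 4520 peaks on chromosome 1, 7.65% had a fold as high as the lowest of the POGK peaks. Among the related pogo and Tigger transposase-derived genes, 1 of 11 had a promoter peak. This was TIGD6, with a fold of 0.89 (0.780 to 1.02), and a peak in an L2 element nearest to TIGD3 had 1.35 (1.16 to 1.57).

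**Figure D1:**
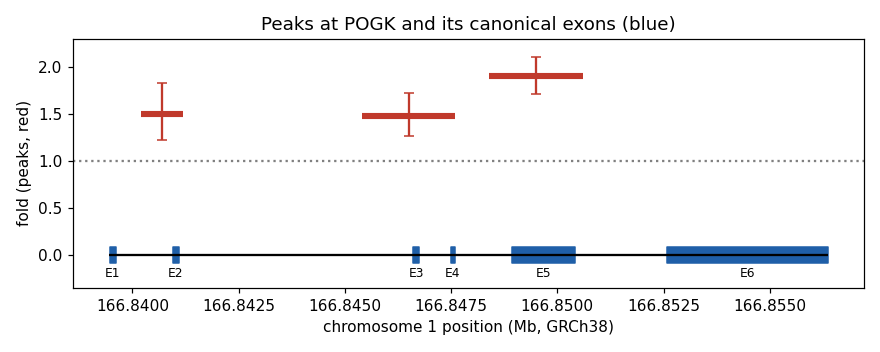
Peaks at POGK on chromosome 1 in GRCh38. The x axis gives the position in Mb and the y axis the fold of scaled ChIP over control tags; red bars are peaks with 95% counting intervals, blue boxes are exons 1 to 6 drawn at an arbitrary height, and the dotted line marks a fold of 1. The peaks have folds of 1.5, 1.48 and 1.90 and exon 6 has no peak.

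Peaks lay near promoters more often than random placement gave, but the promoter peaks had low folds. The peak centre lay within 1 kb of a protein-coding TSS in 5.21% of peaks, 2.98 times (2.86 to 3.10) the 1.75% of random placements. That ratio was 0.862 (0.494 to 1.39) for peaks of at least 2 callers and 0.495 (0.182 to 1.07) for peaks with a fold of at least 2. By the authors' distances, 2854 peaks lay within 1 kb of a RefSeq TSS, and their median fold was 1.03 (1.02 to 1.03) against 1.1 (1.1 to 1.1) in the other 37867 peaks. ChIP was below control in 39.7% of promoter peaks and in 18.4% of the others. Promoter peaks made up 14% (13.2 to 14.7) of peaks with a fold below 1 and 1.44% (0.175 to 5.10) of those with a fold of at least 3. Introns held 46.2% of all peaks and intergenic sequence 42.2%.

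**Figure D2:**
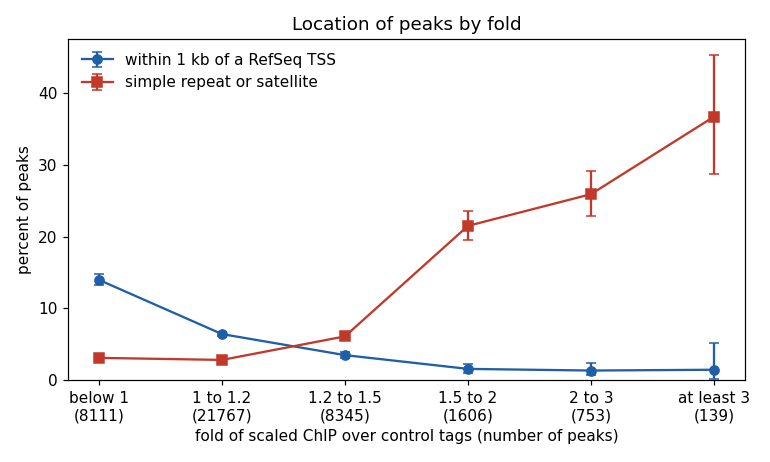
Percent of peaks within 1 kb of a RefSeq TSS (blue circles) and on a simple repeat or satellite (red squares) on the y axis, by the fold of scaled ChIP over control tags on the x axis, with the number of peaks in parentheses and 95% exact binomial intervals as bars. Promoter peaks go from 14% at folds below 1 to 1.44% at folds of at least 3, and simple repeats or satellites from 3.09% to 36.7%.

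Of 2285 protein-coding promoter peaks, at 2239 genes, 17 had a fold of at least 1.5. These 17 were chosen after their values were seen. The highest were at TSPYL6 on chromosome 2 (2.93, 1.77 to 5.07), FAM9B on chromosome X (2.67, 1.85 to 3.94) and SPINK13 on chromosome 5 (2.3, 1.5 to 3.61), all called by MACS2 alone over short intervals. The others included PRR20E, CBLN2, RGS7, NANOGNB, OR4F17, MTRNR2L10, PLSCR2, MAGEE2, C17orf50, C1QTNF9, MAS1L, PROX2 and SRPRB. None belongs to the ribosome, RNA polymerase or translation lists. These lists hold few of the 2239 genes, at most 21 in 1 list (ribosome biogenesis factors), so their absence among 17 decides nothing about them.

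The 5 lists of ribosomal proteins, ribosome biogenesis factors and RNA polymerase I and III were not set apart from random lists under the main rule. That rule needs the peak centre within 1 kb of the TSS. Promoter peaks were present at 7 of 47 large-subunit ribosomal protein genes (14.9%, random mean 11.8%) and 2 of 33 small-subunit genes (6.06%, random 10.7%). They were present at 21 of 137 ribosome biogenesis factors (15.3%, random 12.1%), 5 of 24 RNA polymerase I genes (20.8%, random 11.9%) and 3 of 27 RNA polymerase III genes (11.1%, random 11.9%). The adjusted tail shares of these lists ran from 0.914 to 1.00. Folds were near 1 at RPL22 (1.15, 0.968 to 1.36), RPL5 (1.09, 0.951 to 1.26), the nucleolar factors NOP58 (1.18, 1.00 to 1.40) and NCL (1.14, 0.979 to 1.32), and POLR1D (1.04, 0.923 to 1.17). The fold was lower at RPS6 (0.73, 0.606 to 0.884). In these 5 lists no promoter peak had a fold of at least 1.2 or a second caller, against 230 and 23 of all 2239 genes with a promoter peak. The 5 lists hold few promoter peaks, so the absence of a second caller decides nothing about them. The difference at a fold of 1.2 was not tested. Counting peaks whose centre lay farther off changed 1 call of these 5. With any peak over the window of 1 kb on each side of the TSS, 31 of 47 large-subunit genes (66.0%, random 39.0%, adjusted tail share 0.00216) had one, with a median fold of 1.04 and a highest fold of 1.25. Over the gene body 35 of 47 had one (74.5%, random 47.8%, adjusted tail share 0.00360), and with a peak within 5 kb the list had no call. In the TSS window setting the small-subunit list had 16 of 33 (48.5%, random 35.3%, adjusted tail share 0.384).

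Translation factors had promoter peaks at 12 of 48 genes (25%, random 12%, adjusted tail share 0.153), among them EIF4G3 (1.2, 1.03 to 1.40) and EIF2B5 (1.08, 0.931 to 1.25). These were the 2 highest folds, and the 12 genes had a median fold of 0.97, with 7 below 1. When random lists were matched on chromosome and on coarser length classes, an alternative chosen after seeing the data, the adjusted tail share was 0.0198. Mitochondrial ribosomal proteins had them at 9 of 76 (11.8%, random 11.4%), with folds of 1.23 (1.07 to 1.42) at MRPS22 and 1.2 (1.07 to 1.33) at MRPS31. The lncRNA hosts of small nucleolar RNAs had them at 4 of 27 genes (14.8%, random 1.74%, adjusted tail share 0.0351). This call rested on random lists with 0.469 genes with a peak on average, from a background of which RefSeq, the source of the deposited gene names, names 28.6%. With random lists from genes that RefSeq names, chosen after seeing the data, it ended (random 5.64%, adjusted tail share 0.592). The 4 were SNHG25 (1.18, 1.06 to 1.32), SNHG30 (1.11, 0.953 to 1.30), SNHG20 (1.02, 0.970 to 1.07) and SNHG18 (0.84, 0.740 to 0.948). Any peak over the TSS window, which needs no gene names, gave 14 of 27 (51.9%, random 20.5%, adjusted tail share 0.00216), and any peak over the gene body gave no call (51.9%, random 28.5%, adjusted tail share 0.109). The 13 peaks over the TSS windows had a median fold of 0.97 and a highest fold of 1.18. Of these, 7 had a fold below 1 and none had a second caller.

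Olfactory receptor genes were below random under the main rule, with 7 of 400 genes (1.75%, random 9.77%, adjusted tail share 0.00540). OR4F17 had the highest fold among them (1.75, 1.33 to 2.31). Zinc finger ZNF genes, many of which encode KRAB proteins, had promoter peaks at 81 of 508 genes (15.9%, random 12.1%, adjusted tail share 0.0936), including ZNF430 (1.36, 1.19 to 1.57) and ZNF501 (1.48, 1.24 to 1.78). Without matching on gene length this list was above random (random 11.2%, adjusted tail share 0.0135). With any peak over the TSS window and matching on chromosome and coarser length classes, chosen after seeing the data, it was below (30.5%, random 48.7%, adjusted tail share 0.00135). Protocadherins had 1 of 53 (1.89%, random 10.1%, adjusted tail share 0.247), at PCDHAC1 (1.21, 1.06 to 1.38), and histones 3 of 54 (5.56%, random 8.13%). Both passed the threshold as lists below random with any peak over the TSS window, each with an adjusted tail share of 0.00216, while protocadherins were above random over the gene body (67.9%, random 48.6%, adjusted tail share 0.0391). Over the TSS window 1 of 53 protocadherins and 4 of 54 histones had a peak, the latter from 3 peaks. Random lists drew genes independently, while genes of such families can share a peak, so these tail shares do not count separate loci. The random lists of the main rule and of this TSS window setting were matched on gene length and not on position, while peaks were uneven between regions. A family in a region with few peaks could therefore fall below random for its position. This limit holds for olfactory receptors too. KAP1 and heterochromatin genes had 1 of 25 (4.0%, random 11.5%), at CBX1 (0.98, 0.886 to 1.08).

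**Figure D3:**
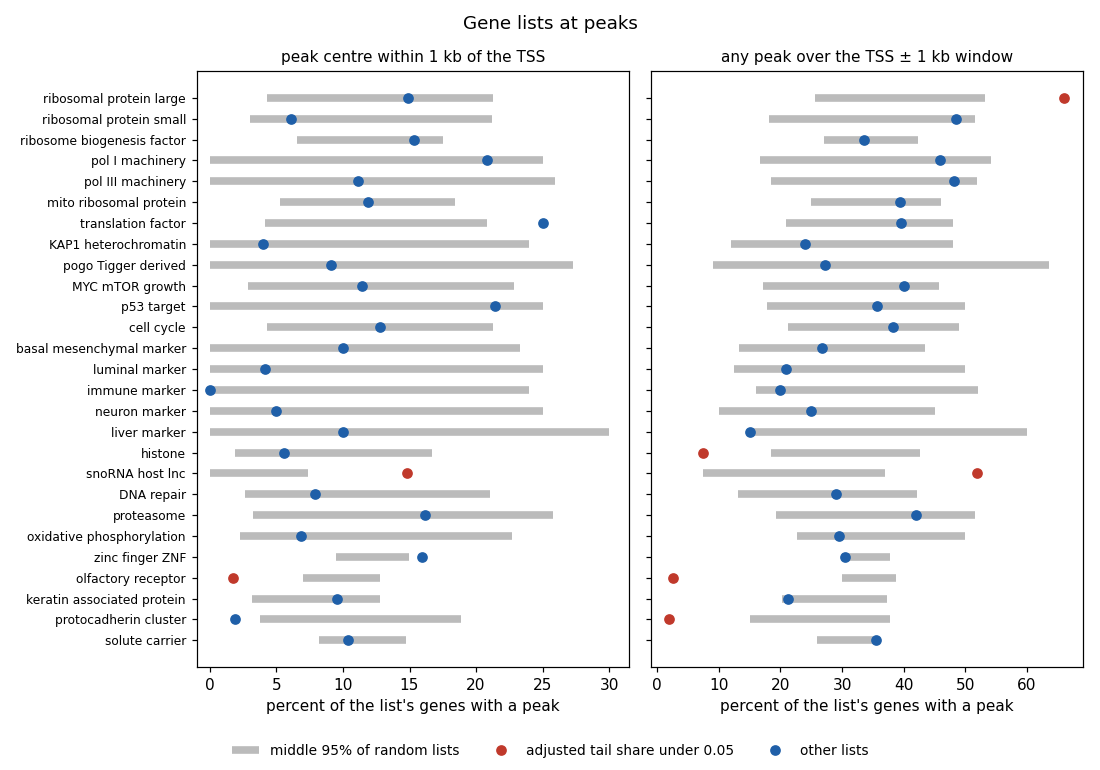
Percent of genes with a peak (x axes) for 27 gene lists (rows), by peak centre within 1 kb of the TSS (left) and by any peak over the window of 1 kb on each side of the TSS (right). Points are the lists, red where the adjusted tail share is under 0.05, and grey bars are the middle 95% of 10000 random lists matched on gene length; on the left 2 lists are red and on the right 5, and the red snoRNA host list on the left is not called with random lists from genes named in RefSeq.

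The remaining lists gave no call under the main rule, and the first promoter peak named for a list had its highest promoter fold. MYC and mTOR growth genes had 4 of 35 (11.4%, random 11.4%), with AKT2 at 1.12 (1.03 to 1.22) and RICTOR at 0.84 (0.764 to 0.927). Cell cycle genes had 6 of 47 (12.8%, random 12.1%), with CDC25C at 1.32 (1.15 to 1.53). DNA repair genes had 3 of 38 (7.89%, random 11.4%), with XRCC2 at 1.34 (1.11 to 1.63). Proteasome genes had 5 of 31 (16.1%, random 12%), with PSMB4 at 1.34 (1.1 to 1.65), a median fold of 0.97 and 3 of the 5 below 1. The p53 targets had 6 of 28 (21.4%, random 11.8%), with XPC at 1.1 (0.914 to 1.32). Oxidative phosphorylation had 3 of 44 (6.82%, random 11.9%), with SDHB at 1.07 (0.928 to 1.23), and solute carriers 38 of 366 (10.4%, random 11.4%), with SLC24A1 at 1.22 (1.08 to 1.38). Keratin-associated proteins had 9 of 94 (9.57%, random 7.59%), with KRTAP10-9 at 1.39 (1.18 to 1.63). In the same setting as for ZNF genes, solute carriers were above random (35.5%, random 29.7%) and keratin-associated proteins below (21.3%, random 33.6%). Basal and mesenchymal markers had 3 of 30 (10%, random 10.9%), including SPARC at 1.16 (1.02 to 1.34), and luminal markers 1 of 24 (4.17%, random 11.5%), KRT18 at 0.98 (0.867 to 1.11). Immune markers had 0 of 25 (random 11.2%). Over the TSS window 5 of these 25 genes had a peak. The highest fold there, 4.21, was that of the HBB peak, centred 1072 bp from the TSS and so outside the main rule. Neuron markers had 1 of 20 (5.00%, random 10.6%), CAMK2A at 1.05 (0.967 to 1.14), and liver markers 2 of 20 (10%, random 12.1%), with APOB at 1.32 (1.13 to 1.54).

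At the ribosomal DNA of chromosome 21, peaks inside the transcribed 45S units had lower ChIP than control signal and most peaks outside them had higher. The 5 peaks centred in the units RNA45SN2 (8205988 to 8219302) and RNA45SN1 (8433222 to 8446572) had folds from 0.43 to 0.74 and a median fold of 0.69. The 15 peaks between and beyond the units had a median fold of 1.28, and 9 of them had at least 3 callers. The peak from 8228275 to 8231199, of all 4 callers, had a fold of 1.42 (1.37 to 1.47). GC content differed too, with a median of 78.3% inside the units and 50.0% outside. The reference holds a few copies of a repeated array, so these tags pool many copies.

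In the 5S array of chromosome 1, a peak of 250 bp called by MACS2 alone within 1 kb of RNA5S1 had a fold of 1.5 (1.07 to 2.12), and the peaks within 1 kb of RNA5S2 and RNA5S12 had 1.07 (0.799 to 1.44) and 1.11 (0.983 to 1.25). A low-complexity, intergenic peak had RNA5S15 as its nearest gene but lay more than 1 kb from it. At the spliceosomal RNA genes RNU5E-1 (1.0, 0.890 to 1.15), RNU1-4 (1.04, 0.923 to 1.18), RNU4-2 (0.97, 0.838 to 1.12) and RNU6-1 (0.90, 0.794 to 1.0) the intervals included 1. The 2 peaks at RNU2-1 had folds of 1.37 (1.15 to 1.62) and 1.19 (0.934 to 1.51). Peaks near the SNAR genes, short non-coding RNA genes that the deposited list types as small nuclear, had folds of 1.51 (1.04 to 2.22) at SNAR-A13, 1.21 (1.07 to 1.37) at SNAR-C3 and 0.93 (0.704 to 1.24) at SNAR-C2. No peak was assigned to 7SK.

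Repeated sequence was common among the peaks with the highest folds and most callers, and Tigger elements, the human relatives of pogo, were not. Simple repeats or satellites held 4.82% (4.61 to 5.03) of all peaks, 20.2% (17.9 to 22.5) of those of at least 2 callers and 65.5% (45.7 to 82.1) of those of all 4. At a fold of at least 3 the share was 36.7% (28.7 to 45.3). Tigger elements lay at 199 peak centres (0.489%, 0.423 to 0.561), with a median fold of 1.1 against 1.09 elsewhere and a highest fold of 2.09. Of these, 5 had at least 2 callers (0.418%, 0.136 to 0.973 of that set). Alu elements lay at 14.4% of all peak centres and at 14.1% of those of at least 2 callers. Peaks of 3 and 4 callers also had median control densities of 681 and 1103 tags per kb, against 108 in all peaks. Median folds fell with GC content, from 1.68 in peaks under 35% GC to 0.925 in those of 70% or more. Shares of repeats under random placement were not computed, so no preference for or against a repeat can be read from these values.

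Peaks were uneven between chromosomes. Chromosomes 20, 19 and 17 had 69.5, 65.0 and 43.2 peaks per Mb, against a genome mean of 13.9. Chromosomes 4, 8, 14 and 18 together had 515 peaks, at 0.964, 1.04, 1.23 and 0.887 per Mb. Peaks with a fold of at least 2 lacked this excess on chromosomes 20, 19 and 17, at 0.172, 0.240 and 0.253 per Mb. On chromosomes 4, 8, 14 and 18 they had 0.148, 0.249, 0.254 and 0.237. Peaks of at least 2 callers kept it, at 1.00, 1.13 and 0.929 per Mb against 0.211, 0.104, 0.0773 and 0.125. The 7 chromosomes with most peaks held 66.6% of them and 31.9% of the gap-free sequence. The 10% of 5 Mb bins with most peaks held 51.3% of peaks, and across the 395 bins with at least 10 peaks, which are not independent replicates, peak number and median fold had a Spearman rho of -0.652. The region of MYC (chromosome 8, 127735434 to 127742951) and PVT1 was one peak of 826.8 kb, from 127382000 to 128208799. Its control signal was 1154 tags per kb, 10.7 times the median of all peaks, and its fold was 0.97 (0.965 to 0.971).

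**Figure D4:**
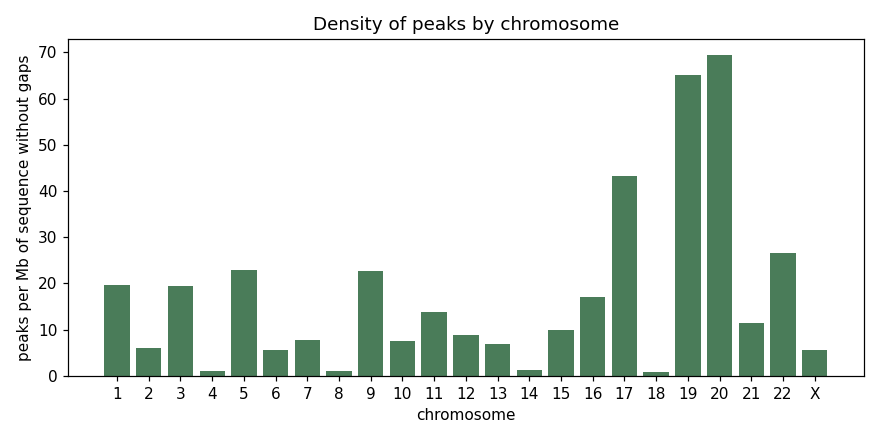
Peaks per Mb of sequence without gaps (y axis) for chromosomes 1 to 22 and X (x axis), all deposited peaks, 1 bar per chromosome. Chromosome 20 has 69.5 and chromosome 18 has 0.887.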

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

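No paired analysis was possible because each peak has 1 pooled value per group, with no columns per replicate. For the same reason TMM and size-factor scaling, a count test, the replicate block and leaving out each replicate were not run. Random placement within 1 Mb of each peak, matching on chromosome and coarser length classes, random lists from genes named in RefSeq and the fold limit of 1.2 were chosen after seeing the data. The cause of the changes below was not tested. The ratio of promoter peaks to random placement (2.98) was 1.92 with a window of 5 kb and 2.08 with placement within 1 Mb. It passed below 1 for peaks of at least 2 callers (0.862) and a fold of at least 2 (0.495), and was 0 for at least 3 callers, all callers and a fold of at least 4, where its intervals reached 1.69 or more. The number of lists called (2) was 0 with at least 2 or 3 callers or a fold of at least 2, which could test no list, and 0 with a fold of at least 1.2, which could test 5. It was 1 with random lists from genes named in RefSeq, where the snoRNA host call ended. Without matching on gene length, 2 lists were called above random and 1 below. In 106 list and setting pairs random lists held under 1 gene with a peak on average, and these gave no value. The number was 4 with a peak within 5 kb, over the gene body, or with matching on chromosome and coarser length classes. It was 5 with either rule of own overlap, and 8 with both own overlap and that matching. Protocadherins passed to above random over the gene body (67.9%, random 48.6%). With own overlap and that matching, ZNF genes (30.5%, random 48.7%) and keratin-associated proteins (21.3%, random 33.6%) were called below random and solute carriers (35.5%, random 29.7%) above. In 47 pairs a list without a call in either setting lay on the other side of its random mean; counting these as unchanged was decided after their number was seen. Of 247 values under other settings 199 were counted as unchanged, and these include the 47 pairs. Simple repeats or satellites (4.82% of peaks) were 20.2% with at least 2 callers, 65.5% with all callers and 27.6% with a fold of at least 2. Tigger elements (0.489%) were 0.418%, 0 and 0.112% in those settings. The 10% of bins with most peaks held 31.7% of peaks with a fold of at least 2, against 51.3%, and 51.5% with at least 2 callers. At least 10 control tags left the median fold at 1.09. The median control count was 413 tags, and the counting interval of the fold included 1 in 23196 of 40721 peaks. Whether this comes from limited depth or from folds near 1 was not separated.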

Other observations

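All tests here were chosen after the results were seen. Outside the ribosome, the immunoglobulin heavy chain locus on chromosome 14 held 5 of the 22 peaks with a fold of at least 4. All 5 lay on variable segments of the IGHV3 family, which has 48 of the 126 annotated IGHV genes. They were IGHV3-7 (106062156 to 106062440, fold 5.69, 3.92 to 8.52), IGHV3-38 (5.76, 3.34 to 10.6), IGHV3-22 (4.28, 2.83 to 6.72), IGHV3-65 (4.06, 2.63 to 6.50) and IGHV3-54, where a peak of 26 bp held 6231 scaled ChIP tags against 81 control tags (76.9, 61.8 to 97). The peaks at IGHV3-38, IGHV3-22 and IGHV3-54 were called by Genrich alone, as were only 8 peaks of the whole list. That at IGHV3-65 was called by MACS2 and Genrich, and that at IGHV3-7 by MACS2, SICER2 and Genrich. The source of so many tags on 26 bp was not tested, and its interval covers counting error only. Another IGHV3 segment, IGHV3-23, had a peak with a fold of 1.28 (1.12 to 1.47). The 4 peaks of the locus outside IGHV genes had folds of up to 1.25.

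Promoter peaks had a lower median fold than other peaks (1.03 against 1.1). GC content averaged over whole peaks did not account for all of this. At matched GC the promoter median was still 0.953 times that of other peaks (0.944 to 0.963), against 0.936 unmatched. The GC of a broad peak averages over its promoter and only called peaks enter, so GC of the promoter itself stays open as the cause. Whether input chromatin holds more DNA of active promoters stays open. In 18 promoter peaks of olfactory receptor, keratin-associated, neuron and liver genes, without OR4F17, whose GC content had no match, the median fold was 1.15, with 1 below 1, against 1.02 in GC-matched promoter peaks, and a share of 0.00050 of 2000 matched sets was as high, the smallest they can give. These are only the called members of their lists, with a median of 108 ChIP tags per kb, near the level that bounds the calls from below, so a locus with few control tags enters only with a high fold. The share was first read in favour of this explanation, and it decides nothing. Avoidance of active promoters by POGK also stays open and untested, since ChIP from vector cells was not analysed here.

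Peaks were crowded on few chromosomes, which may come from calls that follow the absolute density of ChIP tags. Peaks of SICER2 alone of at least 1 kb numbered 36976 outside chromosome Y. On the 19 chromosomes with at least 200 of them, the 5th percentile of ChIP signal was 99 to 105 tags per kb. This is a ratio of 1.06, against 1.19 for control tags. The sparse chromosomes 4, 8, 14 and 18 were left out by that limit. Only called peaks enter, so the common level shows a bound on the calls and not why peaks crowd. Peak number also followed gene number across bins (Spearman rho 0.584 over 631 bins). Copy number cannot be told apart from these: the rho with control density was 0.0654, but that density is bounded below by the calls themselves. This low rho was first read as evidence against copy number, and the reading was withdrawn when that bound was seen. Peak number also changed in steps within chromosomes. On chromosome 5 the bin from 70000001 to 75000000 held 301 peaks and the next bin 7. On chromosome 17 the bin from 15000001 to 20000000 held 11 and that from 25000001 to 30000000 held 227. Gene number and copy number on each side of such steps were not compared. On chromosomes 5 and 8, 8 long peaks with 6.73 to 10.7 times the median control density had folds of 0.94 to 0.98. The 2 other such peaks outside chromosome Y had 1.31 (1.30 to 1.33) on chromosome 10, nearest to LOC441666, and 1.32 (1.31 to 1.34) on chromosome 21, nearest to KCNE1B. No effect of POGK on this pattern was tested.

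The POGK peaks may hold DNA of the introduced POGK sequence, which the ChIP cells carry and the control cells lack. All 3 peaks overlapped coding sequence, as did a share of 0.0924 of 10000 random placements within the gene, and all 4 coding exons had a peak, as in a share of 0.0064. The first share alone had been read against this explanation; the bound set for it forbade nothing, so it was rewritten and the second share added after the first was seen. The 2 shares come from 3 peaks, and binding of POGK at its own gene cannot be told apart from it. No ChIP of vector cells was analysed here.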
